A study of Arabidopsis thaliana with 8 samples.

How the data were processed

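RNA sequencing of Arabidopsis plants, whole plants per the labels, gave 8 libraries in 4 groups of 2: WT and OE (VaWRKY14-overexpressing) plants, each with normal watering and after 5 days without water. Groups were taken from the sample titles. For the first droughted OE library the genotype label names VaWRKY15, against its title and source.

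The authors deposited 1 table per library with an expected count per gene, not normalized, per the file headers, and an FPKM value per gene, also per the file headers. The submitters' processing notes list STAR, HISAT2 2.0.5, featureCounts and edgeR and the genome build TAIR10, without the role or order of the tools. About 88% of the listed counts are whole numbers within 0.005 (88.06% to 88.81% per library). Each table lists only genes with a value above 0, and a gene missing from a table was given a count of 0. The FPKM values were not used here. Reads and alignments were not analysed here.

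In all, 24132 genes were listed in at least 1 library and 20079 in all 8. Gene symbols were taken from the TAIR10.1 annotation by locus name, which matched 23929 genes (99.2%). The order of genes along a chromosome came from the positions in that annotation. No entry names the transgene. Whether strand was used in counting is not stated, so overlapping genes such as MRD1 and HEI10 may share reads.

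Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes with few counts were removed with filterByExpr at its minimum count of 10, which kept 19259 genes, and libraries were scaled by TMM. One quasi-likelihood model with robust estimation and 1 mean per group was fitted to all 8 libraries, which leaves 4 residual degrees of freedom per gene before information is shared between genes. The biological coefficient of variation was 10.2%. The comparisons were OE against WT with normal watering, OE against WT under drought, drought against normal watering in WT, the same in OE, and the difference between these drought responses. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called, with no minimum fold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. For a large change from few counts it can come out too small. For MRD1 it was 0.28 and 0.27 in the 2 conditions but 0.70 for their difference. CPM values use the TMM-scaled library sizes.

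Before the data were examined, 23 gene lists and a rule for naming genes were fixed. The lists were drought and ABA responsive genes, ABA metabolism and signalling, CBF and DREB factors, proline and galactinol metabolism, the WRKY family, salicylic acid and defence, jasmonate, ethylene, antioxidant enzymes, nuclear photosynthesis genes, heat shock, circadian clock, touch and rapid stress, senescence and sugar starvation, cell wall expansion, aquaporins, flavonoid and anthocyanin, glucosinolate, iron homeostasis, cell division, root markers, flower and floral transition, and reference genes. Named were, per comparison, the called genes with a mean of at least 5 CPM and no overlap between the groups' libraries that had the largest change, 8 in each direction (5 for the difference of responses, without the condition on overlap), up to 4 called genes per list with the smallest adjusted p, and 12 fixed markers. Of the genes so chosen, some at only a few counts are given without a fold, and list members past the first examples are given as counts. AT1G25141, AT3G28270 and AT5G03120 were named after their values were seen, as were the genes beside the chromosome 1 loci.

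Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. No call of these lists held with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, was run as well. Members were counted as called over all genes tested and adjusted over the list alone. Overlaps of calls were set beside the overlap of independent lists, and pairs of comparisons without a shared library were used.

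The depth of 9591274 to 11378571 expected counts per library puts 3 counts, the floor used per library for a gene at 0, at 0.242 to 0.313 CPM on the TMM-scaled library sizes. Intervals for low counts are exact 95% intervals and cover counting error only. The spread between the libraries of a group was larger than counting error, with a chi-square per degree of freedom of 5.69 to 9.9. A flower gene score, the mean log2 CPM of AG, AP1, AP3, PI, SEP1, SEP2, SEP3 and A9, was computed per library after the data had been seen.

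The scripts were tested on simulated counts with 200 genes changed and, besides these, the genes of the jasmonate list lowered 1.5-fold. For the comparison of OE with WT plants at normal watering, with 18986 genes tested, 27.4% of genes changed 1.5-fold, 72.7% of those changed 2-fold and 92.3% of those changed 4-fold were recovered, and 19 of 18763 unchanged genes were called. These 19 false calls stand beside 17, 48 and 60 genes recovered at the 3 folds. For the difference of drought responses, with 18980 genes tested, the shares were 3.12%, 38.8% and 78.5%, with 7 of 18754 unchanged genes called. The simulated counts varied gene by gene, without a deviation shared across the genes of 1 library. The shares recovered and the numbers of false calls may therefore not hold for the real libraries.

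The alternatives were a term for the library number, no low-count filter, a filter of at least 5 CPM in 2 libraries, DESeq2 size factors, DESeq2 1.42.0 as the test, only the 4 libraries of the groups compared, a minimum of 2-fold, each library left out in turn and organellar genes left out. A flower gene score as a covariate and a fit without the unstressed libraries numbered 1 were added after seeing the data.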

Results

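Gene expression was measured by RNA sequencing of 3-week-old Arabidopsis plants of the accession Col-0, with whole plants given as the tissue in the labels. The plants were wild type (WT) or overexpressed the grapevine transcription factor VaWRKY14 (OE, described in the labels as a mixture of transgenic plants). Each genotype was sampled with normal watering and after 5 days without water, with 2 libraries in each of the 4 groups. The genotype label of the first droughted OE library names VaWRKY15, while its title and source name VaWRKY14; it was kept in the OE group. The stated purpose of the series was to see which genes change on overexpression with and without drought.

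The 2 unstressed WT libraries held 10871061 and 11378571 expected counts, and the droughted WT libraries 9591274 and 10868040. The unstressed OE libraries held 11211698 and 11325963, and the droughted OE libraries 10904625 and 11074385. Between 21335 and 22290 genes had a value in each library, and 3 counts corresponded to 0.242 to 0.313 CPM, counts scaled to a common library size. LHCB1.3, which encodes a light-harvesting protein of photosystem II, was the most abundant gene in every library except the second droughted WT library, where CAT3 (a catalase) led. The first principal component, with 47.4% of the variance, separated droughted from watered libraries. The second, with 15.2%, had the first unstressed WT library at 41.43 and the first unstressed OE library at -24.77. The transgene has no entry in the deposited tables, so its level was not analysed here.

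The first comparison asked what overexpression changed in watered plants. The largest falls were in MRD1 and HEI10, neighbouring genes on chromosome 1 that overlap in the annotation, the second a factor of meiotic crossover formation. MRD1 (AT1G53480) fell by 6.81 on the log2 scale, with an edgeR adjusted p of 1.14e-09. Its standard error is left out, as its OE counts were few. HEI10 (AT1G53490) fell by 4.51 ± 0.18 (SE, n = 2 per group). MRD1 had 7 counts in the unstressed OE libraries and 846 in WT, which is 0.866% of the WT level (95% interval from counting error 0.347% to 1.79%), and 0.254% and 1.45% without the first and second unstressed OE library. LpxC2 (AT1G24880) rose by 1.94 ± 0.14, from a mean of 202 to 777 CPM, AT1G24996 rose by 1.68 ± 0.13 and LpxC4 by 2.14 ± 0.26. These lie in a stretch of chromosome 1 with near-identical gene copies, so the division of reads among the copies is uncertain.

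Genes named for their induction by cold and drought were also higher in watered OE plants. COR15A, which encodes a protective protein of the chloroplast stroma, rose by 1.69 ± 0.22, from 147 to 473 CPM. COR15B rose by 1.36 ± 0.20, KIN2 by 1.12 ± 0.18, RD29A by 1.12 ± 0.13 and COR413-PM1 by 0.69 ± 0.12. The first and second watered OE libraries were uneven for COR15A (596.1 and 349.5 CPM) and COR15B (563.1 and 399 CPM). COR413IM1 rose by 1.14 ± 0.17, LSU2 by 1.19 ± 0.21 and PP2CA, a phosphatase that damps abscisic acid (ABA) signalling, by 0.76 ± 0.13. Of the markers named in advance, NCED3 stood at 0.94 ± 0.20 (adjusted p = 0.06), RAB18 at 0.87 ± 0.36 (0.419) and RD22 at 0.31 ± 0.15 (0.5). P5CS1 stood at 0.02 ± 0.18 (0.983), PR1 at -1.31 ± 0.96 (0.724) and CAT1 at 0.14 ± 0.11 (0.716). None of these 6 passed the test. RD29B had too few counts to be tested in any comparison. Among the genes that fell, MBP1, a myrosinase-binding protein, changed by -1.08 ± 0.16 and the extensin gene EXT3 by -0.91 ± 0.15. The others named were AT3G51450 (-0.99), EEL (-0.96), MEB1 (-0.90) and AT2G39420 (-0.89).

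**Figure D1:**
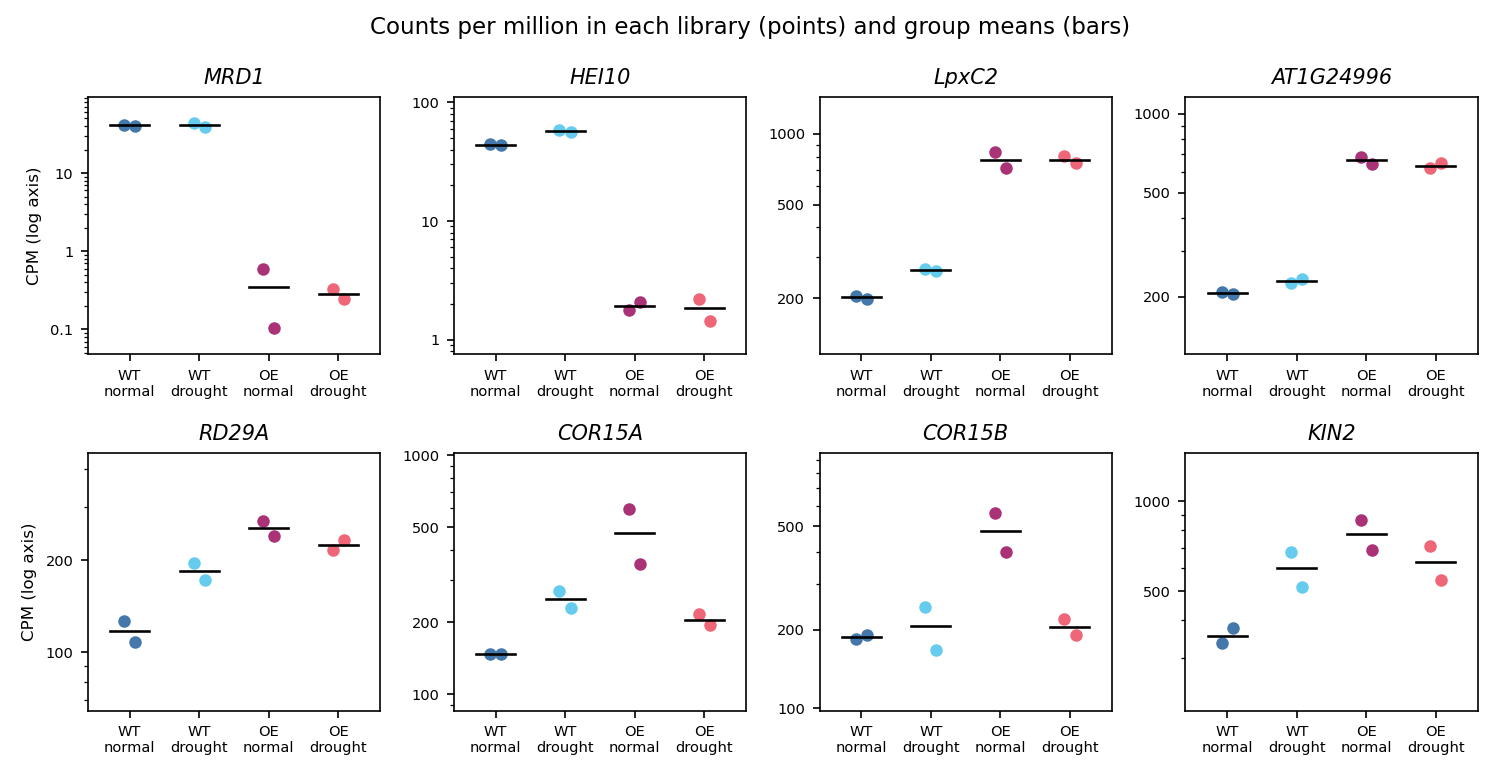
Level (CPM) of 8 genes in each of the 8 libraries (points) with group means (bars), on a log axis, for WT and OE plants with normal watering and under drought. MRD1 and HEI10 are lower in all 4 OE libraries than in any WT library, LpxC2 and AT1G24996 are higher in all 4, and RD29A, COR15A, COR15B and KIN2 are higher in OE than in WT in the watered plants.

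In the drought and ABA responsive list, 5 of 21 tested genes rose and 0 fell in watered OE plants, with a median log2 fold change of 0.41 and a mean of 0.36 over the list. When adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 5.36e-08, and adjusted p = 0.363 with an estimated correlation). In the jasmonate list no gene of 30 was called by edgeR over all genes tested, while 16 fell at an unadjusted p under 0.05, 4 fell with DESeq2 and 9 fell when adjusted over the list alone. Its median log2 fold change was -0.50, with a camera adjusted p of 1.25e-15, and adjusted p = 0.363 with an estimated correlation. All 45 nuclear photosynthesis genes had a positive log2 fold change, with a median of 0.26. Still, edgeR called none of them, 3 passed an unadjusted p under 0.05 and DESeq2 called 1 (camera adjusted p = 1.25e-06, and adjusted p = 0.524 with an estimated correlation). Without the first unstressed WT library the camera call of the photosynthesis list was lost (adjusted p = 0.0616), and without the second that of the drought and ABA responsive list (0.0576). Among cell wall expansion genes, XTH15 rose by 1.09 ± 0.18 and XTH33 by 2.11 ± 0.41, 2 of 17. In that list 5 rose when adjusted over the list alone (camera adjusted p = 0.00139, and adjusted p = 0.363 with an estimated correlation).

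Aquaporins had 0 of 16 genes called by edgeR, 5 that were higher at an unadjusted p under 0.05 and 1 called by DESeq2. In that list 5 rose when adjusted over the list alone (camera adjusted p = 4.58e-05, and adjusted p = 0.363 with an estimated correlation). In the glucosinolate list 1 of 24 genes fell, CYP79B2 by 0.68 ± 0.13, which feeds tryptophan into indole glucosinolates. Of the same list 4 fell when adjusted over the list alone (camera adjusted p = 4.58e-05, and adjusted p = 0.363 with an estimated correlation). The camera test also put the salicylic acid, cell division, flavonoid and flower lists lower, with adjusted p of 8.11e-05, 7.41e-05, 0.000334 and 0.000804. With an estimated correlation the adjusted p = 0.363 for the first pair and adjusted p = 0.4 for the second. The camera call was lost for flavonoid genes without the first unstressed WT library (adjusted p = 0.94), for cell division genes without the second (0.294) and for flower genes without the first unstressed OE library (0.763). In those 4 lists edgeR called no gene, over all genes tested or when adjusted over the list alone. At an unadjusted p under 0.05, 4 salicylic acid, 4 cell division, 2 flavonoid and 0 flower genes were lower, and DESeq2 called 1 salicylic acid gene. The mean log2 CPM of 8 flower genes was 1.77 and 1.38 in the watered WT libraries and -0.359 and 1.44 in the watered OE libraries. The CBF and DREB list was the only one that passed the fry test between OE and WT plants, as higher in watered OE plants (fry adjusted p = 0.0115, median log2 fold change 0.65). Its camera adjusted p was 0.0672, edgeR called 0 of 6 genes, DESeq2 called 0, 3 were higher at an unadjusted p under 0.05 and 1 rose when adjusted over the list alone. Of the ABA metabolism and signalling list 1 of 33 genes rose, and when adjusted over the list alone 3 rose and 1 fell.

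In total 57 genes rose and 18 fell in watered OE plants of 19259 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 22 of the 75 changed at least 2-fold. The count was 438 without the second unstressed WT library, and it was 16 to 26 without the first unstressed WT library, the first unstressed OE library or either droughted WT library. The excess of rises was not kept in 3 fits without 1 library: 136 rose and 302 fell without the second unstressed WT library, 26 rose and 32 fell without the second unstressed OE library, and 9 rose and 10 fell without the first unstressed WT library. With the flower gene score as a covariate, chosen after seeing the data, the count was 8. The score came from the same counts, so this does not tell flower tissue apart from genotype. The calls of LpxC2, AT1G24996, MRD1, HEI10, AT5G03120 and RD29A, 6 of 75, held without each of the 8 libraries in turn, while those of COR15A (adjusted p of 0.141), COR15B (0.156), KIN2 (0.102), COR413-PM1 (0.102) and LpxC4 (0.0795), for example, were lost without the first unstressed WT library. Their log2 fold changes without it were 1.69, 1.33, 1.045, 0.71 and 1.91, so in these 5 the change itself was about as large.

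The second comparison asked what overexpression changed under drought. MRD1 fell by 7.12 on the log2 scale, again from few OE counts, and HEI10 fell by 4.96 ± 0.17 (SE, n = 2 per group). MRD1 had 7 counts in the droughted OE libraries against 921 in WT, 0.697% of the WT level (95% interval from counting error 0.28% to 1.44%). LpxC2 rose by 1.55 ± 0.14, AT1G24996 by 1.46 ± 0.13 and LpxC4 by 2.15 ± 0.25, with the same uncertainty from near-identical copies. GLYI4, of the glyoxalase family, rose by 2.27 ± 0.28, from a mean of 2.01 to 9.70 CPM. AT1G09932 rose by 1.74 ± 0.18, AT1G10340 by 1.51 ± 0.21, the receptor-like kinase gene CRK14 by 1.29 ± 0.17 and AT4G39830 by 1.21 ± 0.20. WRKY53, a regulator of leaf senescence, rose by 0.62 ± 0.11, from 50.2 to 77 CPM.

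Lower in droughted OE plants were the flowering repressor FLC (-1.13 ± 0.20), the anthocyanin regulators PAP2 (-1.01 ± 0.19) and MYBL2 (-0.92 ± 0.12), OPR2 (-0.96 ± 0.18) and MAM3 (-0.71 ± 0.12), an enzyme of aliphatic glucosinolate synthesis. AT5G56840 fell by 1.24, AT3G62960 by 1.23 and AT4G19430 by 1.00. None of the 11 tested markers named in advance passed the test under drought. RD29A stood at 0.29 ± 0.13 (adjusted p = 0.501), COR15A at -0.29 ± 0.21 (0.749), COR15B at -0.01 ± 0.20 (0.996), KIN2 at 0.07 ± 0.17 (0.942) and COR413-PM1 at -0.01 ± 0.12 (0.983). NCED3 stood at 0.43 ± 0.20 (0.532), P5CS1 at 0.43 ± 0.18 (0.499), RAB18 at 0.22 ± 0.30 (0.883), RD22 at 0.01 ± 0.14 (0.989), PR1 at 0.94 ± 1.21 (0.881) and CAT1 at -0.05 ± 0.11 (0.946).

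In the salicylic acid and defence list, 23 of 24 genes had a positive log2 fold change in droughted OE plants, with a median of 0.42. The edgeR test called 0 of them over all genes tested, DESeq2 called 0 and an unadjusted p under 0.05 was met by 7. In that list 6 rose when adjusted over the list alone (camera adjusted p = 7.87e-09, and adjusted p = 0.502 with an estimated correlation). The list's median was 0.235 without the second droughted WT library and 0.794 without the first. All 20 cell division genes had a positive log2 fold change, with 0 called by edgeR, 0 by DESeq2 and 7 at an unadjusted p under 0.05. Of these 2 rose when adjusted over the list alone (camera adjusted p = 8.92e-08, and adjusted p = 0.502 with an estimated correlation). In the flavonoid and anthocyanin list 2 of 23 fell. When adjusted over the list alone 1 rose and 7 fell (camera adjusted p = 0.000203, and adjusted p = 0.502 with an estimated correlation), and the camera call was lost without the second droughted WT library (0.111).

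In the flower list 1 of 13 genes fell (FLC). When adjusted over the list alone 3 rose and 1 fell, with the list as a whole up (camera adjusted p = 0.00206, and adjusted p = 0.502 with an estimated correlation). The flower gene score was 3.32 and 2.90 in the droughted OE libraries and 2.18 and 2.29 in the droughted WT libraries. Touch and rapid stress genes were shifted up (camera adjusted p = 7.49e-05) and circadian genes down (0.00226), as were antioxidant enzymes and aquaporins (0.0215 for both lists). For these 4 lists adjusted p = 0.502 with an estimated correlation. No gene of these 4 lists was called by edgeR. At an unadjusted p under 0.05, 2 touch genes were higher and 3 circadian, 3 antioxidant and 1 aquaporin genes were lower, and DESeq2 called 1 antioxidant gene. When adjusted over the list alone, 1 circadian gene and 1 aquaporin gene fell and no gene of the other lists was called. In the senescence list 1 of 18 genes rose, and 2 when adjusted over the list alone (camera adjusted p = 0.0215, and adjusted p = 0.502 with an estimated correlation). Of these camera calls, those of the circadian (0.113) and senescence lists (0.437) were lost without the second droughted WT library, and those of the antioxidant (0.423) and aquaporin lists (0.739) without the first. The flower (0.103) and aquaporin calls (0.054) were lost without the first droughted OE library, and the antioxidant (0.119) and aquaporin calls (0.0628) without the second. WRKY53 was the only one of 47 WRKY genes called, and when adjusted over the list alone 3 rose and 2 fell.

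Under drought 31 genes rose and 26 fell in OE plants (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 27 of the 57 changed at least 2-fold. The count was 129 and 130 without the first and second unstressed WT library, 30 and 23 without the first and second droughted OE library and 10 without the second droughted WT library, of which 4 rose and 6 fell. Without the first droughted WT library 46 rose and 16 fell, without the first and second droughted OE library 16 and 18 rose and 14 and 5 fell, and with only the 4 libraries compared 151 rose and 82 fell. The calls of AT1G09932, LpxC2, AT1G24996, LpxC4, MRD1 and HEI10, 6 of 57, held without each of the 8 libraries in turn.

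The genes called between OE and WT plants in both conditions came mostly from a pair of places on chromosome 1. LpxC2, LpxC4, AT1G24996 and AT1G25141 rose in both, 4 genes where 0.0918 would be shared by independent lists. MRD1, HEI10 and AT3G28270 fell in both, 3 genes where 0.0243 would be shared. Of these 7 genes, 6 lie at those loci, and none of the 7 was called for a difference between the conditions. Genes of 1 locus that may share reads are not independent cases, so the excess over the values for independent lists is overstated. The summed level of all 13 listed genes of the duplicated stretch was 1632 ± 121 CPM (SD, n = 2) in watered OE plants and 473 ± 5.41 in watered WT plants, and 1618 ± 31.5 against 564 ± 0.274 under drought. The genes on either side did not follow: MAP70-2 had log2 ratios of -0.19 and 0.09, ASB1 of -0.55 and 0.22, AT1G53460 of -0.19 and -0.07, and MUM4 of -0.06 and 0.15, without and with drought. Across all genes tested, which are not independent replicates, the log2 fold changes of OE against WT in the 2 conditions had a Pearson correlation of 0.0793 and a Spearman correlation of -0.125.

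The third comparison was the drought response of WT plants. GLN1;4, a cytosolic glutamine synthetase, rose by 3.83 ± 0.17 (SE, n = 2 per group), from a mean of 13.1 to 187 CPM. The sucrose transporter gene SWEET13 rose by 3.63 ± 0.25, the anthocyanin regulator PAP2 by 4.39 ± 0.27 and GSTF12, which carries anthocyanins to the vacuole, by 3.62 ± 0.43. NUDT24 had 0 counts in the watered WT libraries and a mean of 15.66 CPM under drought, which is at least 53.9-fold higher, taking 3 counts per library as the floor. BOR5 rose by 3.53, AT1G80130 by 3.48 and AT1G34060 by 3.47.

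The defensin genes PDF1.3, PDF1.2A, PDF1.2B and PDF1.2C, whose near-identical sequences leave the division of reads among them uncertain, changed by -7.59 ± 0.75, -5.005 ± 0.66, -5.57 ± 0.55 and -5.22 ± 0.95. BT2 fell by 5.47 ± 0.44, from 389 to 8.96 CPM, and AT3G15356 fell by 4.34 ± 0.73, from 173 to 8.62 CPM. DIN11 had 3 counts in the droughted WT libraries against 347 in the watered ones, 0.792% of the watered level (95% interval from counting error 0.163% to 2.33%), with 285 and 62 counts in the watered libraries. The share was 2.23% and 0.479% without the first and second watered library, and 0.482% and 1.17% without the first and second droughted library. AT4G36850 had 9 counts against 252, 3.27% of the watered level (1.48% to 6.31%), and from 1.99% without the first droughted library to 4.83% without the second. Of the markers named in advance, RD29A rose by 0.65 ± 0.13 (adjusted p = 0.00351), KIN2 by 0.75 ± 0.18, COR15A by 0.77 ± 0.22 and RD22 by 0.53 ± 0.15. COR15B stood at 0.13 ± 0.20 (0.73), COR413-PM1 at 0.22 ± 0.12 (0.259), and NCED3 at 0.09 ± 0.21 (0.834). P5CS1 stood at -0.12 ± 0.18 (0.721), RAB18 at 1.07 ± 0.35 (0.057), PR1 at -3.23 ± 1.11 (0.163) and CAT1 at -0.10 ± 0.11 (0.626). These 7 did not pass.

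Photosynthesis genes fell together in droughted WT plants: 38 of 45 fell, 44 when adjusted over the list alone, with a median of -0.95 (camera adjusted p = 9.69e-25). RBCS3B, a small subunit of Rubisco, fell by 1.55 ± 0.20, PSBQ1 by 1.24 ± 0.16 and RBCS2B by 1.39 ± 0.20, with the reads of the RBCS and LHCB copies hard to divide. In the jasmonate list 13 of 30 genes fell, 14 when adjusted over the list alone (camera adjusted p = 6.53e-10). Among them were LOX2 (-1.95 ± 0.19), which starts jasmonate synthesis in the chloroplast, CORI3 (-2.05 ± 0.18), JAZ1 (-1.29 ± 0.17) and MYC2 (-0.76 ± 0.14). In the salicylic acid list 6 of 24 fell, 9 when adjusted over the list alone (camera adjusted p = 2.04e-08), with CBP60G at -0.83 ± 0.13 and EDS1 at -0.63 ± 0.14. Of the glucosinolate list 1 rose and 12 fell of 24, and 1 rose and 14 fell when adjusted over the list alone (camera adjusted p = 4.9e-07). MAM3 was the gene that rose, by 0.89 ± 0.13, and CYP79B2 fell by 0.94 ± 0.13. For these 4 lists adjusted p = 0.3 with an estimated correlation.

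Touch and rapid stress genes fell in 5 of 13 cases, 9 when adjusted over the list alone (camera adjusted p = 1.57e-06), with TCH3 at -1.46 ± 0.18. Flavonoid and anthocyanin genes rose in 14 of 23 cases, and when adjusted over the list alone 19 rose and 1 fell (camera adjusted p = 6.3e-12), with F3H at 1.90 ± 0.22 and UGT79B1 at 3.13 ± 0.30. The drought and ABA responsive list had 8 of 21 genes that rose, 12 when adjusted over the list alone (camera adjusted p = 4.02e-06). In ABA metabolism and signalling 9 rose and 1 fell of 33, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000642). CYP707A2, which breaks ABA down, rose by 2.25 ± 0.25 and PP2CA by 0.95 ± 0.13. BGLU18, which releases ABA from its glucose ester, fell by 1.42 ± 0.22. Circadian genes rose in 5 of 17 cases, 8 when adjusted over the list alone (camera adjusted p = 0.00196), with CCA1 at 2.16 ± 0.36. Ethylene genes fell in 3 of 16, 5 when adjusted over the list alone (0.0036). In the flower list only FLC was called, by 1.13 ± 0.20 (camera adjusted p = 0.0209, and 0.105 and 0.0733 without the second unstressed and the second droughted WT library). With an estimated correlation the adjusted p = 0.588 for this list, and adjusted p = 0.3 with an estimated correlation for the other lists called here.

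Several lists were split in droughted WT plants. Among 13 proline and galactinol genes 3 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone. GOLS2 (galactinol synthesis) stood at 1.88 ± 0.14, PRODH1 (proline breakdown) at 1.73 ± 0.27 and P5CS2 (proline synthesis) at -0.65 ± 0.12. Of 47 WRKY genes 4 rose and 7 fell, and 4 rose and 9 fell when adjusted over the list alone. WRKY44 stood at 1.80 ± 0.31, WRKY33 at -0.79 ± 0.14 and WRKY70 at -0.71 ± 0.15. Of 19 antioxidant genes 2 rose and 2 fell, and 2 rose and 5 fell when adjusted over the list alone, with FSD1 at -1.48 ± 0.27 and GPX1 at -1.19 ± 0.15. Among 16 aquaporins 1 rose and 2 fell, and 1 rose and 3 fell when adjusted over the list alone, with PIP2;2 at -0.81 ± 0.13. Of 17 cell wall genes 2 rose and 3 fell, and 3 rose and 5 fell when adjusted over the list alone. Of 12 iron genes 2 rose and 3 fell, the same counts as when adjusted over the list alone. SEN1, at -1.62 ± 0.22, was 1 of 2 senescence genes of 18 that fell, 2 also when adjusted over the list alone. CBF3, at 1.64 ± 0.36, was the gene called of 6 CBF and DREB factors, 1 also when adjusted over the list alone. No heat shock gene of 11, cell division gene of 20 or reference gene of 9 was called by edgeR. An unadjusted p under 0.05 was met by 1, 3 and 3, DESeq2 called 0, 0 and 2, and 0, 0 and 2 were called when adjusted over the list alone.

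In droughted WT plants 1085 genes rose and 1420 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 583 of the 2505 changed at least 2-fold. The count was 1118 without the second droughted WT library and 1635 without the second unstressed WT library, and 771 calls held without each of the 8 libraries in turn.

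**Figure D2:**
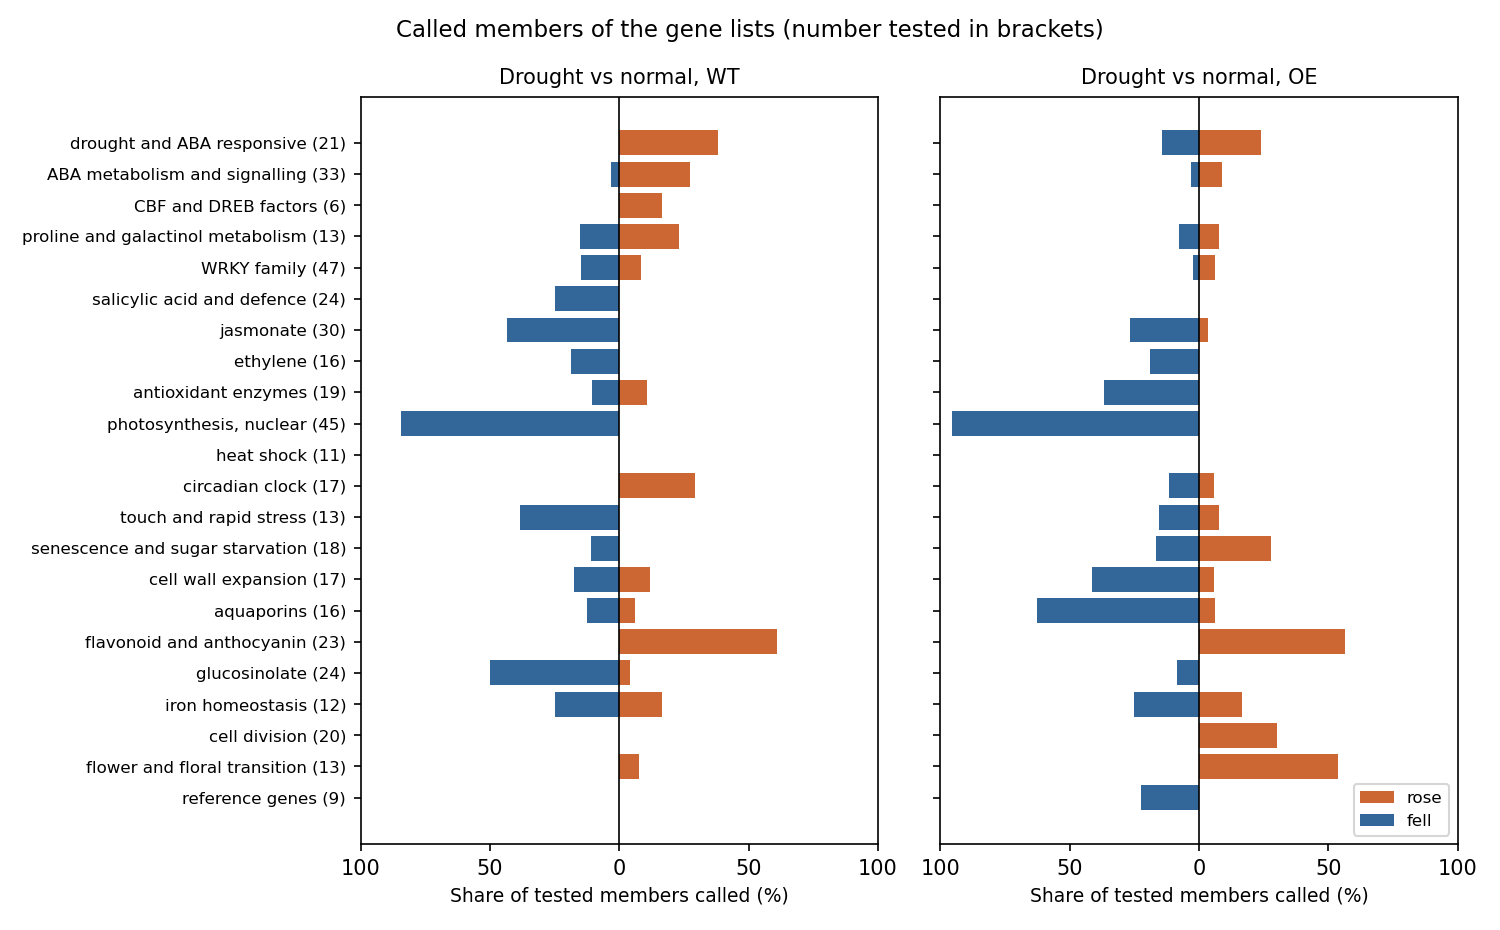
Share of the tested members of 22 gene lists that rose (right) or fell (left) under drought, in percent, in WT plants and in OE plants, with the number tested in brackets. Photosynthesis genes fell in both genotypes (38 and 43 of 45) and flavonoid genes rose in both (14 and 13 of 23).

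The fourth comparison was the drought response of OE plants. SAG12, a protease gene used as a marker of leaf senescence, had 0 counts in the watered OE libraries and a mean of 122 CPM under drought, at least 401-fold higher. The droughted libraries stood at 185 and 58.6 CPM, and the bound was 193-fold without the first and 609-fold without the second. In WT plants SAG12 had 1 and 0 counts with normal watering and 63 and 55 under drought. BGLU30, a gene of sugar starvation, also had 0 counts in the watered OE libraries and 13.7 CPM under drought, at least 45.1-fold higher. CSLA01 had 1 and 3 counts in the watered OE libraries and a mean of 11.7 CPM under drought, and is given without a fold. AT2G20870 rose by 4.57 ± 0.88 (SE, n = 2 per group), AT1G09500 by 4.11 ± 0.83 and AT5G22430 by 3.71 ± 0.67. LAP5, a gene of pollen wall synthesis, rose by 3.45 ± 0.40 and PAP2 by 3.27 ± 0.28. The watered OE libraries were uneven for AT2G20870 (0.79 and 4.79 CPM), AT5G22430 (1.28 and 4.06) and LAP5 (0.296 and 1.67). The largest falls were in PDF1.3 (-6.33 ± 0.72), BT2 (-4.45 ± 0.41), PDF1.2B (-3.76 ± 0.54), PDF1.2A (-3.502 ± 0.62) and LHCB1.4 (-3.05 ± 0.50), with the PDF1 and LHCB1 copies uncertain. AT1G49500 (-2.96 ± 0.61), the gibberellin-responsive GASA1 (-2.76 ± 0.48) and AT2G21210 (-2.74 ± 0.32) followed.

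Of the markers named in advance, COR15A (-1.21 ± 0.21, adjusted p = 0.00478), COR15B (-1.23 ± 0.20) and COR413-PM1 (-0.49 ± 0.12) fell on drought in OE plants, from the higher levels of the watered OE plants. For COR15A and COR15B the watered OE libraries were uneven, as given above. RD29A stood at -0.18 ± 0.13 (0.361), KIN2 at -0.30 ± 0.17 (0.258), RD22 at 0.23 ± 0.15 (0.306) and NCED3 at -0.42 ± 0.19 (0.14). P5CS1 stood at 0.28 ± 0.18 (0.32), RAB18 at 0.42 ± 0.31 (0.389), PR1 at -0.97 ± 1.05 (0.603) and CAT1 at -0.29 ± 0.11 (0.0971). These 8 did not pass.

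Photosynthesis genes fell in 43 of 45 cases in droughted OE plants, 44 when adjusted over the list alone (camera adjusted p = 4.51e-31), with RBCS3B at -2.04 ± 0.21 and PSAN at -1.64 ± 0.17. Flavonoid and anthocyanin genes rose in 13 of 23 cases, and when adjusted over the list alone 18 rose and 1 fell (camera adjusted p = 2.8e-11), with F3H at 1.89 ± 0.22 and CHIL at 1.65 ± 0.22. Flower genes rose in 7 of 13 cases, 11 when adjusted over the list alone (camera adjusted p = 3.88e-07), with SEP2 at 2.94 ± 0.51, PI at 2.07 ± 0.33 and FUL at 1.09 ± 0.17. Cell division genes rose in 6 of 20, 9 when adjusted over the list alone (5.09e-06), with CYCA1;1 at 0.91 ± 0.21. The flower gene score was -0.359 and 1.44 in the watered and 3.32 and 2.90 in the droughted OE libraries, a wider gap than in WT plants. For these 4 lists adjusted p = 0.342 with an estimated correlation.

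Aquaporins had 1 gene that rose and 10 that fell of 16, with the same counts when adjusted over the list alone (camera adjusted p = 0.000373), among them PIP2;2 (-1.11 ± 0.13) and TIP2;2 (-1.01 ± 0.12). Antioxidant enzymes fell in 7 of 19 cases, with the same count when adjusted over the list alone (0.024), ethylene genes in 3 of 16, likewise (0.016), and glucosinolate genes in 2 of 24, likewise (0.0229). For these lists too, adjusted p = 0.342 with an estimated correlation. The camera calls of ethylene (0.204), antioxidant and glucosinolate genes (0.0732 for both) were lost without the second unstressed OE library. Those of ethylene (0.0595) and glucosinolate genes (0.0939) were also lost without the first droughted OE library, and that of antioxidant genes without the second (0.0512). The jasmonate list did not pass (camera adjusted p = 0.0524), with 0.453 and 0.174 without the second unstressed and the first droughted OE library. It passed as lower without each of the other 6 libraries, from 0.00155 without the first unstressed OE library to 0.0478. In it 1 rose and 8 fell of 30, and 2 rose and 9 fell when adjusted over the list alone, with LOX2 at -1.36 ± 0.19 and AOC2 at -0.99 ± 0.17.

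In the drought and ABA responsive list 5 rose and 3 fell of 21, and 5 rose and 4 fell when adjusted over the list alone, with ATHB12 at 1.41 ± 0.19. The list's median was -0.01, its mean 0.44 and its camera adjusted p 0.771. ABA metabolism had 3 genes that rose and 1 that fell of 33, also when adjusted over the list alone, with HAI2 at 1.56 ± 0.29 and the ABA receptor gene PYL5 at -1.43 ± 0.21. In the senescence list 5 rose and 3 fell of 18, also when adjusted over the list alone. Of 17 cell wall genes 1 rose and 7 fell, or 2 and 8 when adjusted over the list alone, with XTH8 at -1.25 ± 0.16. WRKY genes had 3 that rose and 1 that fell of 47, and 2 and 1 when adjusted over the list alone, with WRKY53 at 1.05 ± 0.12 and WRKY22 at -0.94 ± 0.20. Iron genes had 2 that rose and 3 that fell of 12, also when adjusted over the list alone, with FER1 (ferritin) at -1.15 ± 0.15. The list's median and mean were above 0 in both drought responses while its camera direction was down, and it was not called. ACT2 (-0.78 ± 0.14) and ACT8 (-0.61 ± 0.13) were 2 of 9 reference genes that fell, 2 also when adjusted over the list alone. In the salicylic acid list edgeR called 0 of 24 genes, DESeq2 1, an unadjusted p under 0.05 was met by 2 that rose and 2 that fell, and 0 were called when adjusted over the list alone.

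In droughted OE plants 1303 genes rose and 1911 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 692 of the 3214 changed at least 2-fold. The count was 2053 and 1768 without the first and second unstressed OE library, 1456 and 1569 without the first and second droughted OE library, and 898 calls held without each of the 8 libraries in turn. With the flower gene score as a covariate, an alternative chosen after seeing the data, 206 genes were called, 11 that rose and 195 that fell, of which 169 were among the 3214. Of the 3214, 78 had the opposite sign with that covariate, none of them called there. The score came from the same counts and was higher in both droughted than in both watered OE libraries. It therefore takes up part of the drought contrast, and the lost calls do not tell flower tissue apart from drought.

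The drought responses of the 2 genotypes shared many genes. WT and OE plants had 389 genes that rose in both, where independent lists would share 73.4, and 869 that fell in both, where independent lists would share 141. Only 4 genes that rose in WT fell in OE, and 8 that fell in WT rose in OE. Across all genes tested, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.525 and a Spearman correlation of 0.52.

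The fifth comparison tested whether the drought response differed between OE and WT plants. AT1G35710, a receptor-like kinase gene, went from 559 to 277 CPM in WT and from 414 to 579 CPM in OE on drought, a difference of 1.496 ± 0.21 (log2, SE, adjusted p = 0.0099). AT4G03450 differed by 2.00 ± 0.34, AT1G21313 by 1.88 ± 0.29, AT1G10340 by 1.71 ± 0.29, AT1G09932 by 1.42 ± 0.26 and WRKY53 by 0.89 ± 0.16, each with the more positive response in OE plants. GLN1;4 had the more positive response in WT plants, by a difference of -1.73 ± 0.22, as had AT1G34060 (-1.70 ± 0.25), AT3G59580 (-1.99 ± 0.33), AT5G25240 (-1.52 ± 0.21) and OPR2 (-1.496 ± 0.27). COR15A missed the threshold at -1.98 ± 0.30 (adjusted p = 0.0502), as did RD29A at -0.83 ± 0.18 (0.0703), COR15B at -1.36 ± 0.28 (0.0786), COR413-PM1 at -0.71 ± 0.17 (0.0881) and KIN2 at -1.05 ± 0.25 (0.0924). NCED3 (-0.51 ± 0.28), P5CS1 (0.41 ± 0.25), RAB18 (-0.65 ± 0.47), RD22 (-0.30 ± 0.21), PR1 (2.25 ± 1.54) and CAT1 (-0.19 ± 0.16) did not pass either.

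**Figure D3:**
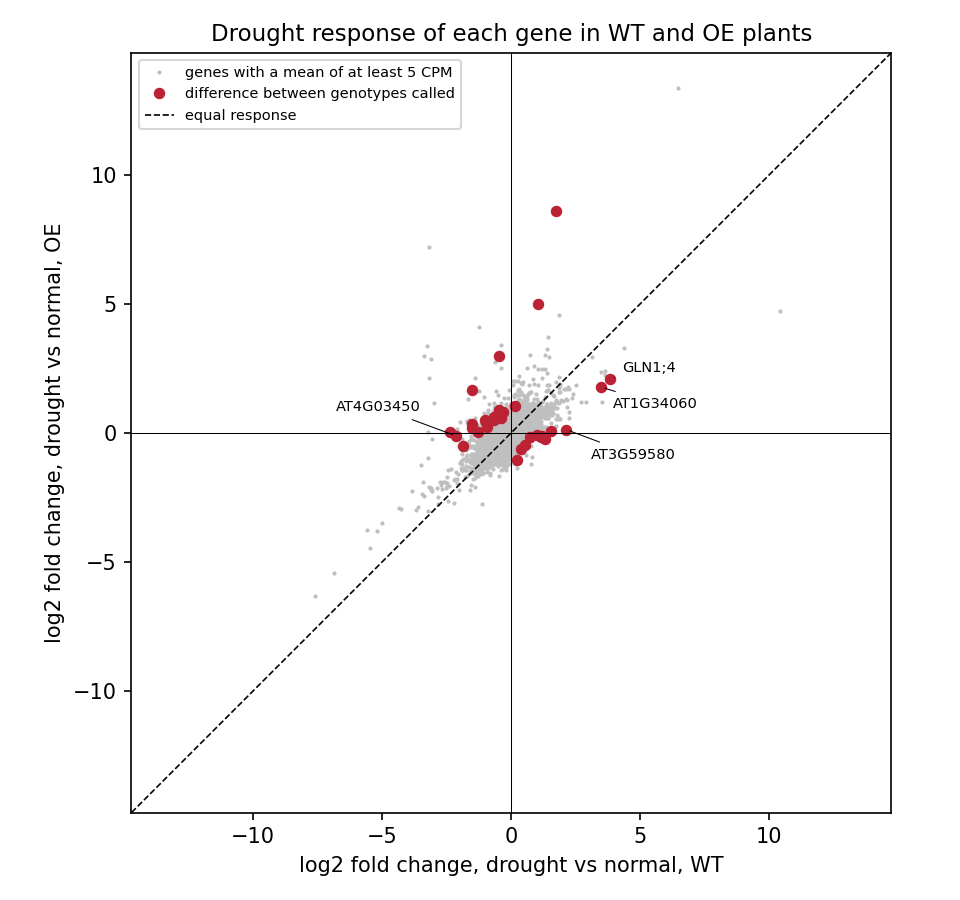
Log2 fold change of each gene on drought in WT plants (horizontal axis) and OE plants (vertical axis), for genes with a mean of at least 5 CPM (grey) and for the 31 genes whose response differed between the genotypes (red); the dashed line marks equal responses. Fitted folds of genes with almost no counts in one group, at the edges, are not bounds. GLN1;4 lies below the line and AT4G03450 above it.

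In the salicylic acid list all 24 genes had the more positive drought response in OE plants, with a median difference of 0.79 (camera adjusted p = 6.58e-11). The edgeR test called 0 of them and DESeq2 1, an unadjusted p under 0.05 was met by 9, and 3 were called when adjusted over the list alone. All 20 cell division genes also had the more positive response in OE plants (2.37e-09), with 0 called by edgeR, 0 by DESeq2, 13 at an unadjusted p under 0.05 and 7 when adjusted over the list alone. The jasmonate list (3.71e-07), with 25 of 30 differences above 0, and the flower list (3.65e-05), with 12 of 13, were also shifted up. The edgeR test called none of their genes, and 7 in each were higher at an unadjusted p under 0.05. In the other direction 1 flower gene was lower at an unadjusted p under 0.05 and DESeq2 called 1 flower gene as lower, while it called 1 jasmonate gene as higher. Adjusted over the list alone 0 jasmonate genes and 7 flower genes (6 up, 1 down) were called. For these 4 lists adjusted p = 0.403 with an estimated correlation. The flower gene score was higher under drought than with watering in every library of both genotypes, with the wider gap in OE plants.

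Aquaporins (1.86e-05), drought and ABA responsive genes (0.000143) and photosynthesis genes (0.000323) were shifted down. The edgeR test called none of them, 7, 9 and 1 were lower at an unadjusted p under 0.05, DESeq2 called 1, 5 and 0 as lower, and 4, 8 and 0 fell when adjusted over the list alone. Of the drought and ABA responsive genes 1 was higher at an unadjusted p under 0.05, and 1 rose when adjusted over the list alone. For aquaporins and drought genes adjusted p = 0.403 with an estimated correlation, and for photosynthesis adjusted p = 0.598. The camera call of the drought list was lost without the second unstressed WT library (0.195), and that of photosynthesis genes without the first unstressed (0.155) or the first droughted WT library (0.306). Further shifts, up for touch (0.000588), glucosinolate (0.00337), senescence (0.00988) and WRKY genes (0.0398) and down for ABA metabolism (0.00988) and circadian genes (0.0165), had an adjusted p of 0.403 or 0.452 with an estimated correlation. When adjusted over the list alone, 1 touch, 1 senescence and 3 WRKY genes were more positive in OE plants, glucosinolate had 2 more positive and 1 more negative, ABA metabolism 1 and 4, and circadian 1 more negative. Among these, the glucosinolate call held without each library in turn. Without the first unstressed OE library the calls of touch (0.171), ABA metabolism (0.0802) and WRKY genes (0.2004) were lost, and without the second that of circadian genes (0.0766). Senescence (0.296) and WRKY calls (0.113) were lost without the first unstressed WT library, and the ABA metabolism call (0.125) without the second. The WRKY call (0.0551) was lost without the first droughted WT library, and the senescence (0.139), circadian (0.132), ABA metabolism (0.105) and WRKY calls (0.0779) without the second. Circadian (0.0542) and WRKY calls (0.0734) were lost without the first droughted OE library, and the ABA metabolism call (0.0543) without the second.

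The drought response differed in 31 genes, with 19 more positive and 12 more negative in OE plants (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The count was 326 and 51 without the second and first unstressed WT library, 142 and 13 without the second and first unstressed OE library, 7 without the second droughted WT library and 2 without the second droughted OE library. The balance of directions changed as well. Without the second and first unstressed WT library 234 and 33 were more positive and 92 and 18 more negative, and without the second and first unstressed OE library 97 and 6 against 45 and 7. Without the first and second droughted WT library 35 and 1 were more positive and 9 and 6 more negative, and without the first and second droughted OE library 7 and 1 against 14 and 1. In all, 0 of the 31 calls held without each of the 8 libraries in turn. With the flower gene score as a covariate, 1 gene was called and it was not among the 31. Here too the score takes up part of the contrast tested, so the loss decides nothing about flower tissue.

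The labels give whole plants as the tissue, yet of the root markers 6 of 15 had no value in any library and only the potassium channel gene AKT1, at a mean of 18.4 CPM, could be tested; the highest of the others reached 0.74 CPM. AKT1 was not called in any comparison. The labels do not say whether the libraries of a group came from separate plants or cultures, so every p-value here measures only the spread between these samples.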

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

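Leaving out each library in turn and the test of the difference of responses were planned, while their use to weigh an explanation, and the tests on summed levels, on the difference between conditions at the loci, on clock genes, on the drought list against droughted WT plants and on the flower gene score, were chosen only after the results were seen. The drought response differed between OE and WT plants in 31 genes, by the test of the difference itself. Those named were AT4G03450 (log2 difference 2.00), AT1G21313 (1.88), AT1G10340 (1.71), AT1G35710 (1.496), AT1G09932 (1.42), WRKY53 (0.89), AT3G59580 (-1.99), GLN1;4 (-1.73), AT1G34060 (-1.70), AT5G25240 (-1.52) and OPR2 (-1.496). None of the 31 calls held without each of the 8 libraries in turn (edgeR; 2407 genes had an unadjusted p under 0.05, and DESeq2 called 146 with all libraries).

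Genes of 2 loci on chromosome 1 differed between OE and WT plants in both conditions, LpxC2 and its neighbours upward and MRD1 and HEI10 downward. An uneven division of reads among near-identical copies would leave the summed level of the region alike, but the sum over its 13 listed genes was higher in OE plants, with a log2 ratio of group means of 1.52 in the condition where it was smaller (1.499 in the lowest pair of libraries). The sum of MRD1 and HEI10 was lower, with -5.22 the ratio of group means nearer to 0 (-5.15 in the nearest pair). A DNA difference between the plant lines at these loci would act alike in both conditions and may account for the pattern: the largest difference between conditions among the shared genes there was 0.449 on the log2 scale, with none called. Steady regulation by the transgene predicts the same, so these cannot be told apart with 1 set of transgenic plants, whose DNA was not analysed here.

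Drought and cold marker genes (COR15A, COR15B, KIN2, RD29A and COR413-PM1) were higher in OE than in WT plants without stress, by a mean of 1.2 on the log2 scale. These are the 5 that were called of the 21 tested genes of the drought and ABA responsive list, whose median was 0.41 and mean 0.36; NCED3, RAB18, RD22 and P5CS1, named in advance, did not pass. The values argue against a different hour of harvest large enough to move clock genes alike, whose median absolute change was 0.189 (interquartile range 0.134). A share of 1 unusual library could not be excluded for the drought and ABA responsive list. Without the second unstressed WT library its median was 0.276, and without the first it was 0.701. The median standard error of single genes of the list was 0.2 in the fit with all libraries. An error of the list median was not estimated, so these values cannot decide. The mean of the 5 called markers stayed at 1.01 to 1.35 without each of the 8 libraries in turn, but they were picked for passing. A weaker form of the WT drought response could not be excluded either. It would leave drought genes below their level in droughted WT plants. Over the 21 tested genes of the drought and ABA responsive list the median log2 ratio of watered OE to droughted WT plants was 0.103. The interquartile range across these genes was 0.789, with 12 genes higher and 9 lower, of which edgeR called 4 and 5. Those called higher were COR15A, COR15B, RD29A and COR413-PM1. The 5 marker genes were higher by a mean of 0.693, but they had been picked for being high in the same OE libraries, which leaves this value without weight. A direct or indirect effect of the transgene and an earlier stage of a stress response, for which the series has no time points, stay open as untested hypotheses.

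In the salicylic acid and defence list 23 of 24 genes had a positive log2 fold change in OE against WT plants under drought, with a median of 0.42. Still, edgeR and DESeq2 called 0 of 24, 7 had an unadjusted p under 0.05, and the list had an adjusted p of 0.502 with an estimated correlation, so the shift is not established. The second droughted WT library may account for part of it, since without it the median was 0.235, and without the first 0.794. The median standard error of single genes of the list was 0.294 in the fit with all libraries. An error of the list median was not estimated, so the part of this library cannot be decided. More flower tissue in the droughted OE libraries could not be tested sharply either, since the slope of the list's score on the flower gene score within groups was -0.00313 with an interval of -0.81 to 0.804, which includes the 0.608 that the difference would need. An effect of the transgene on this list stays open, untested.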

How the results depend on the processing

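The flower gene score covariate and the fit without the unstressed libraries numbered 1 were chosen after seeing the data; the other alternatives were fixed before. Of 5627 values of named genes and lists, 4869 kept their side of the threshold, 687 lost it, 70 gained it and 1 reversed. The reversal was in the photosynthesis list in OE against WT plants under drought, which was not called with all libraries, was up without the first droughted WT library (camera adjusted p of 0.00106) and down without the second (0.000156, the lowest without 1 library, with 0.786 the highest); the cause was not tested. With the flower covariate 78 of the 3214 genes called for drought in OE plants had the opposite sign, none of them called there. The counts below are in the order OE against WT watered, OE against WT under drought, drought in WT, drought in OE, and difference of responses, against 75, 57, 2505, 3214 and 31. Requiring 2-fold gave 22, 27, 583, 692 and 28, which follows from its construction. Without a low-count filter the counts were 166, 108, 2654, 3403 and 202, and with DESeq2 171, 91, 1925, 2271 and 146. With only the 4 libraries compared they were 21, 233, 2104 and 3737. The flower covariate gave 8, 27, 2051, 206 and 1, of which 7, 12, 1820, 169 and 0 were called in the fit without it. Its score came from the same counts and differed between the groups, so these losses do not show that flower tissue was the cause. Leaving out both unstressed libraries numbered 1 gave 16, 224, 2176, 2449 and 19, of which 7, 57, 1726, 2015 and 5 were shared. Apart from the 2-fold minimum, the cause was not tested. Without 1 library in turn, where the lone library of a group is assumed to vary like the others, the counts ranged from 16 to 438, 10 to 130, 1118 to 2578, 1456 to 3562 and 2 to 326. The stricter filter, DESeq2 size factors and organellar genes left out kept every count within 1.5 times. DESeq2 had 32.8% and 29.5% of its drought calls rising in WT and OE, against 43.3% and 40.5%.

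At an adjusted p under 0.01 the drought responses shared 151 genes that rose and 419 that fell, against 389 and 869, as fewer genes pass. A replicate block, with library number as a term, gave 75, 63, 2397, 3047 and 44, but libraries of the same number did not pair (correlations of their deviations across groups -0.0804 to 0.0625). Camera with an estimated correlation ended all 51 list calls. The fry test kept 17, of which 9 were in the drought response of WT and 8 in that of OE plants, kept 0 of the 32 in the other 3 comparisons, and gained 8, of which 1 was in those 3, the CBF and DREB list in watered OE plants (0.0115). FPKM alternatives were not run, as the tables hold expected counts. Depth limits genes under about 0.3 CPM, and the low-count filter also left root markers of up to 0.74 CPM untested. Changes of 1.5-fold were recovered in 27.4% of simulated cases for watered OE against WT plants and in 3.12% for the difference of responses.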

Other observations

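The nitrate list described here was chosen after its values were seen, so its counts and medians describe these genes and test nothing. Genes of nitrate uptake, reduction and signalling were lower after drought in both genotypes. In WT plants 10 of 15 genes fell, with a median log2 fold change of -2.09 (edgeR with Benjamini-Hochberg adjustment). In OE plants 11 of 15 fell, with a median of -1.90. The nitrate reductase gene NIA2 changed by -3.09 in WT and -2.20 in OE plants, the nitrite reductase gene NIR1 by -2.09 and -1.93, and the vacuolar nitrate exchanger gene CLC-A by -2.88 and -2.13. The nitrate-responsive regulators LBD37, LBD38 and LBD39 changed by -2.43, -3.06 and -2.56 in WT plants and by -2.08, -2.26 and -1.90 in OE plants.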
